A study of Arabidopsis thaliana with 9 samples.

How the data were processed

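RNA sequencing libraries were made from total RNA of whole seedlings of Arabidopsis thaliana harvested at 7 days of age at ZT20, that is 20 hours after the lights came on, under short days, per the labels' protocols. The labels give 3 genotypes, wild type (Col-0), the cop1-6 mutant and the cor27cor28 double mutant, with 3 libraries each, sequenced on an Illumina HiSeq X instrument. They describe separate samples but do not say whether these came from separate batches of plants.

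The deposited values are FPKM, fragments scaled by transcript length and by the library's mapped fragments, 1 value per gene and library. The submitters' processing notes name Trimmomatic 0.36, HISAT2 2.2.1.0, Cufflinks, TopHat, Bowtie2 and DESeq 1.18.0 and the TAIR10 genome build. Per those notes no role or order is attached to a tool, so which of them made the deposited FPKM is not given in the sources used here, and neither is whether strand was used. Each library had 26997 entries, of which 13 carried no gene name. Those held between 0.000197% and 0.00203% of a library's FPKM sum and were left out. All 26984 remaining genes matched the TAIR10.1 annotation by identifier, which supplied symbols and coordinates, and 4512 of them were listed at 0 in all 9 libraries. No gene encoded in the chloroplast or mitochondrial genome was among them. COP1 was not analysed here.

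The number of reads per library is not given in the sources used here, and FPKM does not carry it, so no counting interval or detection limit was computed. A value of 0 is described only as listed at 0. The spacing of the low FPKM values (at most 0.5), compared between libraries with a kernel bandwidth of 0.02, gave relative depths between 0.998 and 1.06, an indirect measure only. FPKM sums ranged from 515929 to 612462. FPKM is relative to the rest of its library, so a change in a few abundant genes, or in total RNA, shifts all other values.

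A count-based test had been planned, with limma on log2(FPKM + 1) fixed as the fallback for a normalized unit, and the fallback was used because the values are FPKM. Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, which left 17075. This minimum was set once the unit was known, as was the replacement of a mean of 10 CPM by a mean of 10 FPKM in the rule for named genes. A linear model with the 3 genotypes as groups was fitted to all 9 libraries in limma 3.58.1 under R 4.3.3, with a trend of the variance on expression. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and are given with the standard error of the model. Group values are mean ± SD of FPKM over 3 libraries. The calling step was tested on simulated data for 17075 genes with 50 genes changed at each size. At a 2-fold change it recovered 72% for cop1-6 against wild type, 72% for cor27cor28 against wild type and 78% for cop1-6 against cor27cor28. At a 1.5-fold change recovery was 44%, 52% and 40%, at a 4-fold change 96%, 94% and 92%, and at a 1.25-fold change 4%, 8% and 6%. False calls made up 8.47%, 4.24% and 3.57% of the calls. Far fewer genes were changed in the simulation than were called in the data. The adjusted p threshold was therefore harder to pass there, and these shares do not carry over directly to the comparisons.

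The groups, comparisons, fallback test, rule for named genes, 20 gene lists and most alternative settings were fixed before the data were examined. The lists were morning-phased clock genes, evening-phased clock genes, light signalling regulators, shade and PIF target genes, auxin-responsive genes, cell wall loosening and synthesis, gibberellin and brassinosteroid metabolism, the flavonoid and anthocyanin pathway, light-harvesting antenna, nuclear-encoded photosystem core with the Rubisco small subunit, chlorophyll biosynthesis, cold-regulated genes, flowering time genes, dark and sugar starvation genes, jasmonate and salicylate defence, glucosinolate biosynthesis, mitotic cell cycle, root tissue markers, seed tissue markers and common reference genes. They held 358 members, of which 353 were analysed and 293 passed the FPKM minimum. The shade list shared IAA19 and IAA29 with the auxin-responsive list and EXPA8 and XTH15 with the cell wall list. It also shared DWF4 with the gibberellin and brassinosteroid list, so results of these lists are not independent. All listed genes were matched by identifier. For 7 of them the list's symbol was not found in the annotation: RVE6, UGT75C1, DVR, CDF5, PRX57, TIP41-LIKE and SAND keep the list's names here. Genes could be named if they were COR27, COR28, PIF4, HY5, FT, CCA1, PRR5 or TOC1. From each list up to 3 called members with the lowest adjusted p could be named, and in addition the 6 highest and 6 lowest fold changes among called genes with a symbol, a mean of at least 10 FPKM and no overlap between the libraries of both groups. This rule gave 73, 66 and 74 genes for the 3 comparisons, of which the text names a part. Genes of the closing section that fall outside it were chosen after their values were seen.

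Each list was tested against all other tested genes with camera (limma) at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 40 tests for both mutants against wild type and over 20 tests for the mutants against each other. Alternatives were camera with the correlation estimated from the libraries, and fry, which tests whether a list's genes move, on balance, one way, without comparing them with other genes. For the overlap of both mutants, 50 pairs of unchanged groups were simulated against the same wild-type values. Further alternatives were a pseudocount of 0.1, no minimum FPKM, fits on 2 groups only, the replicate number as a block, and leaving out each library in turn. Added after the unit was seen were median-of-ratios scaling of the FPKM values, rescaling to equal totals in all libraries, and a mean FPKM of at least 1 as the minimum. No pair of libraries was a duplicate, since the most alike pair differed in 99.9953% of the values. Near-identical paralogs, among them SAUR19 to SAUR24, SAUR63 to SAUR67, the LHCB1 and LHCB2 genes, the RBCS genes, KIN1 and KIN2, GSTF6 and GSTF7 and the PIP aquaporins, could share reads, so their separate values are uncertain.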

Results

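Transcript levels were measured by RNA sequencing in 7-day-old seedlings of Arabidopsis thaliana grown in short days and harvested at ZT20, late in the night phase of the day. There were 3 groups of 3 libraries. Wild type was Col-0, the standard laboratory strain. The cop1-6 mutant carries an allele of COP1, which encodes a ubiquitin ligase that marks light-signalling transcription factors for degradation in darkness. The cor27cor28 mutant is a double mutant of COR27 and COR28, which encode small nuclear proteins regulated by cold and by the circadian clock. The FPKM values of a library summed to between 584878 and 612462 in wild type, between 515929 and 532655 in cop1-6 and between 548055 and 562621 in the libraries labelled cor27cor28. Between 16062 and 16974 genes per library had at least 1 FPKM. Across genes, log2(FPKM + 1) correlated within a group at r = 0.978 to 0.991 and between groups at r = 0.931 to 0.979, and genes are not independent replicates. The first principal component held 61.3% of the variance and set the cop1-6 libraries apart from the other 6, and the second, with 18.4%, set wild type apart from the libraries labelled cor27cor28. In cop1-6 replicate 3, 177 genes were at least 2 times higher than in both other cop1-6 libraries, against 3 to 29 such genes in the other 8 libraries. Because separate batches of plants are not stated, p-values measure only the spread between these samples.

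The targeted genes were examined first. COP1 was not analysed here, so the cop1-6 label was not checked on its own gene. COR27 (AT5G42900, chromosome 5, 17197641 to 17199910 on the minus strand of TAIR10.1) had 12.5, 17.4 and 16.2 FPKM in the wild-type libraries and 2.45, 6.71 and 7.46 FPKM in the cop1-6 libraries. In the libraries labelled cor27cor28 it had 48.0, 50.1 and 47.9 FPKM, 3.17 times the wild-type mean (log2 fold change 1.62 ± 0.26 SE, adjusted p = 0.00165). COR28 (AT4G33980, chromosome 4, 16282281 to 16285229 on the minus strand) had 2.73, 1.92 and 3.08 FPKM in wild type and 0.134, 0.245 and 0.130 FPKM in cop1-6. It had 2.49, 1.48 and 2.71 FPKM in the libraries labelled cor27cor28, which did not pass the test (log2 fold change −0.16 ± 0.19 SE, adjusted p = 0.573). Neither targeted transcript was therefore called lower than in wild type in the libraries labelled cor27cor28. The positions and kinds of the lesions are not given in the sources used here, so these transcript levels do not check the label, and every direction given below rests on the labels of wild type and of both mutants alone.

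**Figure D1:**
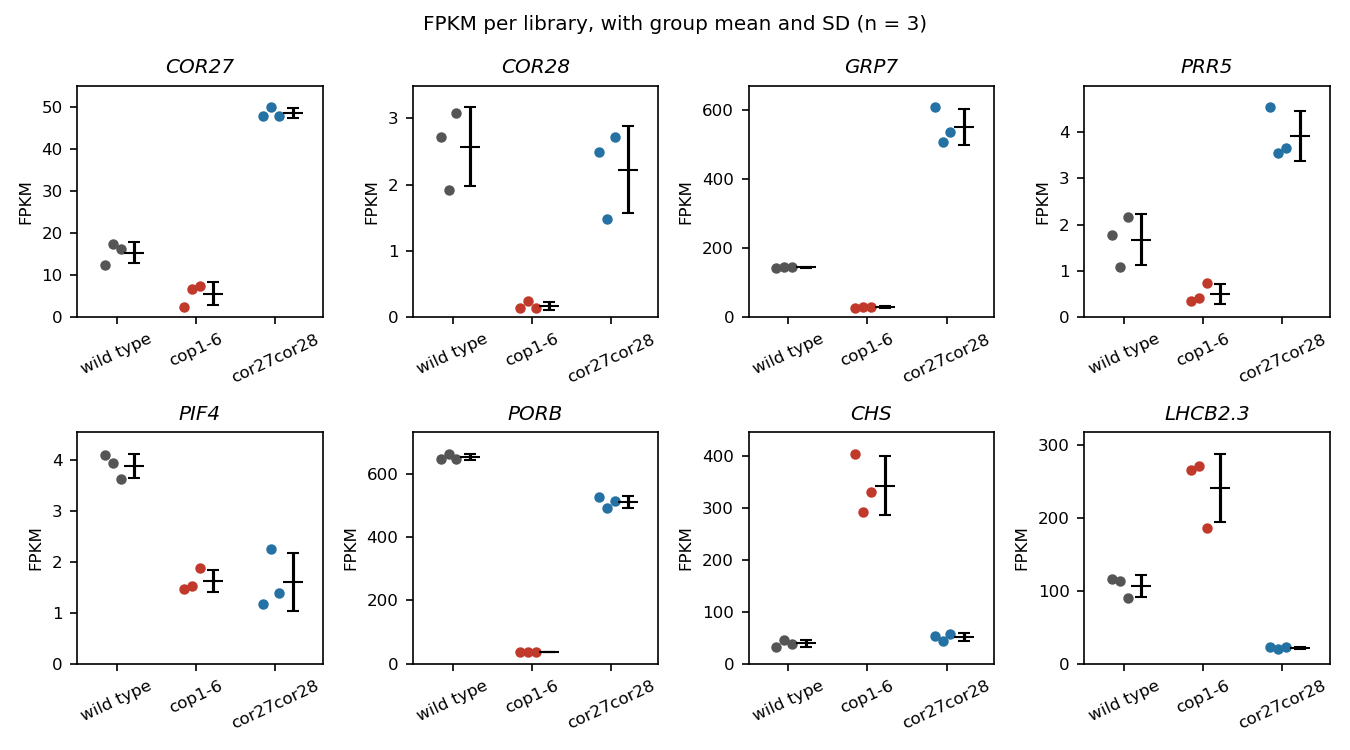
FPKM of 8 genes in each of the 9 libraries (vertical axes, FPKM, each from 0), with points for single libraries of wild type, cop1-6 and the libraries labelled cor27cor28 and, beside them, the group mean with its SD (n = 3). COR27 and GRP7 lay highest in the 3 libraries labelled cor27cor28 and lowest in cop1-6, PORB lay at 36.5 ± 0.956 FPKM in cop1-6 against 653 ± 9.42 in wild type, and PIF4 lay below wild type in both mutants.

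The comparison of cop1-6 with wild type asks which transcripts depend on COP1 at night. Flavonoid genes and early light-induced genes were higher in cop1-6, and auxin-responsive, shade-responsive and glucosinolate genes were lower. ELIP1 and ELIP2, which encode chlorophyll-binding proteins of light stress, rose 180.3 and 102 times, to 129 ± 15.2 and 239.7 ± 11.1 FPKM from 0.714 ± 0.327 and 2.35 ± 0.287 (SD, n = 3; log2 fold changes 6.25 ± 0.15 and 6.17 ± 0.10 SE). PORB, which encodes a protochlorophyllide oxidoreductase, was 17.9 times lower, at 36.5 ± 0.956 against 653 ± 9.42 FPKM (log2 fold change −4.12 ± 0.06 SE, adjusted p = 1.26e-12). All 17 tested flavonoid and anthocyanin genes rose, while 19 of 25 auxin-responsive genes and 16 of 19 shade and PIF target genes fell.

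Among the flavonoid genes, CHS, which encodes chalcone synthase at the entry of the pathway, rose from 38.7 ± 7.01 to 342 ± 57.1 FPKM (log2 fold change 3.12 ± 0.15 SE, adjusted p = 1.54e-08). The flavonol synthase gene FLS1 rose from 10.8 ± 1.26 to 76.4 ± 10.5 FPKM and the flavanone hydroxylase gene F3H from 5.09 ± 1.23 to 32.4 ± 4.11 FPKM. The list's median log2 fold change was 1.1 and it stood apart from the other genes (camera adjusted p = 1.12e-18, and adjusted p = 0.0722 with an estimated correlation). Of 27 light signalling regulators, 15 rose and 7 fell (camera adjusted p = 1.31e-06, and adjusted p = 0.165 with an estimated correlation). Without cop1-6 replicate 3, 11 rose and 7 fell. The B-box gene BBX32 rose from 1.60 ± 0.320 to 30.1 ± 3.54 FPKM, and RUP1 and RUP2, whose products repress the UV-B receptor, had log2 fold changes of 1.85 and 2.54. HY5, the transcription factor gene best known downstream of COP1, was not called (log2 fold change −0.08 ± 0.13 SE, adjusted p = 0.666), and PIF4, a growth-promoting transcription factor gene on chromosome 2 (17886101 to 17889087), fell from 3.89 ± 0.244 to 1.62 ± 0.226 FPKM. Other genes with large rises were SQP1, at 110.0 ± 19.9 FPKM against 3.22 ± 0.915, and the thionin gene THI2.2, at 79.5 ± 11.1 against 2.6 ± 0.470 FPKM. The glucosyltransferase gene UGT74E2 rose from 1.72 ± 1.03 to 25.7 ± 9.23 FPKM.

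Auxin-responsive, shade and cell wall genes were lower in cop1-6. The auxin-responsive list had a median log2 fold change of −1.22 (camera adjusted p = 9.66e-05, and adjusted p = 0.329 with an estimated correlation). IAA29, an auxin-signalling repressor gene, fell from 8.05 ± 1.54 to 0.196 ± 0.115 FPKM and GH3.6, an auxin-conjugating enzyme gene, from 37.0 ± 1.52 to 12.7 ± 1.51 FPKM. SAUR22 fell too, with a log2 fold change of −2.87, though near-identical SAUR copies make its own value uncertain. The shade and PIF target list had a median of −1.20 (camera adjusted p = 0.00058, and adjusted p = 0.392 with an estimated correlation), and ATHB2, a homeodomain gene of the shade response, fell from 11.3 ± 2.13 to 2.72 ± 0.620 FPKM. Of 21 cell wall genes, 12 fell and 1 rose, against 11 and 5 with median-of-ratios scaling and 11 and 4 with equal totals (camera adjusted p = 0.0374, and adjusted p = 0.412 with an estimated correlation). The expansin genes EXPA3 and EXPA8 had log2 fold changes of −1.69 ± 0.08 and −2.48 ± 0.15 SE, and XTH4, a xyloglucan-modifying enzyme gene, fell from 462 ± 49.6 to 139 ± 8.49 FPKM. Of 12 gibberellin and brassinosteroid genes, 5 fell and 2 rose, and 5 and 1 without cop1-6 replicate 3, and the list did not pass (camera adjusted p = 0.718). Those that fell included the brassinosteroid synthesis genes DWF4 and CPD (log2 fold changes −1.20 and −1.05) and also BAS1, whose product inactivates brassinosteroids (−0.95). GA3OX2, on the same list, had at least 1 FPKM only in the 3 cop1-6 libraries, so it was not tested without replicate 3.

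The clock lists parted in cop1-6. Of 12 morning-phased genes, 7 rose and 2 fell (camera adjusted p = 0.000201, and adjusted p = 0.293 with an estimated correlation). Of 10 evening-phased genes, 8 fell and 0 rose (camera adjusted p = 0.0139, and adjusted p = 0.165 with an estimated correlation), against 7 and 1 with median-of-ratios scaling. CCA1, a central morning transcription factor gene, rose from 39.5 ± 4.72 to 77.0 ± 6.19 FPKM (log2 fold change 0.95 ± 0.11 SE, adjusted p = 1.94e-05). TOC1, which represses it, fell from 21.0 ± 1.80 to 8.02 ± 1.26 FPKM (log2 fold change −1.29 ± 0.11 SE, adjusted p = 2.42e-06), and PRR5 fell from 1.67 ± 0.555 to 0.5 ± 0.207 FPKM. LNK1 and LNK4 rose (log2 fold changes 2.54 and 2.1), while RVE2, also on the morning list, fell from 383 ± 17.8 to 107 ± 14.3 FPKM. BOA and CHE, on the evening list, had log2 fold changes of −2.26 and −1.86. COR27 and COR28 fell as well (log2 fold changes −1.41 ± 0.26 and −1.60 ± 0.19 SE).

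The photosynthesis lists did not pass in cop1-6, and how many of their genes rose and fell depended on the scaling. Of 20 antenna genes, 6 rose and 12 fell with the deposited values, 8 rose and 5 fell with median-of-ratios scaling, and 7 rose and 8 fell with equal totals (camera adjusted p = 0.764). The list's median (−0.37) and mean (−0.13) were negative while camera placed it above the other genes. LHCB4.3 and LHCB2.2 rose (log2 fold changes 2.2 and 0.99) and LHCB1.4 fell from 507 ± 63.8 to 78.6 ± 3.55 FPKM, with near-identical copies making the LHCB1 and LHCB2 values uncertain. Of 25 photosystem core and Rubisco genes, 1 rose and 15 fell, against 5 and 4 with median-of-ratios scaling and 5 and 5 with equal totals (camera adjusted p = 0.325). PSBQ2, a photosystem II gene, fell from 1512 ± 125 to 752 ± 63.4 FPKM. Of 17 chlorophyll synthesis genes, 3 rose and 6 fell, against 7 and 1 with median-of-ratios scaling and 6 and 3 with equal totals, and 4 and 4 without cop1-6 replicate 3 (camera adjusted p = 0.583). Its median (−0.08) and mean (−0.26) were negative and camera placed it above the other genes. CHLH, a magnesium chelatase subunit gene, rose from 357 ± 15.5 to 588 ± 46.9 FPKM.

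Of 13 glucosinolate synthesis genes, 11 fell and 0 rose (camera adjusted p = 0.00442, and adjusted p = 0.204 with an estimated correlation), among them CYP79B3, CYP83A1 and MAM1 with log2 fold changes of −1.45, −1.60 and −1.26. Of 6 tested root markers, 5 fell (camera adjusted p = 0.00414, and adjusted p = 0.155 with an estimated correlation). They included CASP1 and CASP2, which encode proteins of the Casparian strip in the root endodermis, and CASP1 fell from 12.7 ± 2.28 to 0.444 ± 0.411 FPKM. All 4 tested seed markers rose (camera adjusted p = 0.00148, and adjusted p = 0.293 with an estimated correlation), at low levels and with a wide spread. OLEO1 had at least 1 FPKM only in the cop1-6 libraries (1.58, 5.31 and 1.14), and CRU1 passed the FPKM minimum only through them. For both the minimum itself favoured a rise in cop1-6, so the list's count and test add no independent support. The seed storage protein gene CRU1 had 8.66 ± 4.65 FPKM against 0.458 ± 0.607 in wild type. Without cop1-6 replicate 3, 3 seed markers rose, and OLEO1 had too few libraries at the FPKM minimum to be tested. With equal totals, where more genes were tested, 7 rose. Of 10 mitotic genes, 9 fell, but 2 with median-of-ratios scaling and 4 with equal totals, and the list did not pass (camera adjusted p = 0.0661) but did with median-of-ratios scaling (adjusted p = 0.0448). CYCD3;1, a cyclin gene, had a log2 fold change of −0.67. Of 15 cold-regulated genes, 5 rose and 7 fell, and 3 and 7 without cop1-6 replicate 3 (camera adjusted p = 0.831), and COR414-TM1 and COR47 fell (log2 fold changes −2.89 and −1.52). Of 14 flowering time genes, 2 rose and 6 fell, against 3 and 2 with median-of-ratios scaling and 3 and 4 with equal totals (camera adjusted p = 0.771, placed above the other genes while its median of −0.23 and mean of −0.18 were negative). The floral repressor genes FLC and SVP fell (log2 fold changes −1.21 and −0.88). FT, the florigen gene, was below the FPKM minimum for testing and had 0, 0.164 and 0 FPKM in wild type, 0.735, 0.507 and 0.335 in cop1-6, and was listed at 0 in the 3 libraries labelled cor27cor28. Of 12 dark and sugar starvation genes, 1 rose and 6 fell, against 2 and 4 with median-of-ratios scaling (camera adjusted p = 0.303), and DRM1 fell from 98.7 ± 7.54 to 14.3 ± 4.43 FPKM. Of 11 defence genes, 2 rose and 1 fell (camera adjusted p = 0.162), and without cop1-6 replicate 3 the numbers were 2 and 3. Of 8 common reference genes, 5 fell and 0 rose, against 3 and 1 with median-of-ratios scaling and 3 and 0 with equal totals and without cop1-6 replicate 3 (camera adjusted p = 0.194), and ACT2, an actin gene, fell from 345 ± 12.5 to 209.5 ± 6.90 FPKM.

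In all, 8448 of 17075 tested genes were called in cop1-6 against wild type, 1865 higher and 6583 lower, and 442 and 892 of them had at least a 2-fold change. The median log2 fold change of all tested genes was −0.21 in cop1-6 against wild type, 0.10 in the libraries labelled cor27cor28 against wild type and −0.36 between the mutants, and single changes are to be read relative to these shifts. Of the called genes 77.9% were lower with the deposited values, 47.7% with median-of-ratios scaling and 57.2% with equal totals, so the split between higher and lower calls in cop1-6 changed with the scaling. Adjusted over the list alone, the counts above were the same except for 8 light regulators lower, 1 auxin-responsive gene higher and 20 lower, 7 chlorophyll synthesis genes lower, 8 cold-regulated genes lower and 10 mitotic genes lower. Of the 20 lists, 10 passed with camera in this comparison, and 0 with an estimated correlation. The one camera call of all 3 comparisons that held with an estimated correlation was the flavonoid list between the mutants (adjusted p = 0.0188). With fry, which tests whether a list's genes move, on balance, one way and not whether they differ from other genes, 18 of 20 passed.

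**Figure D2:**
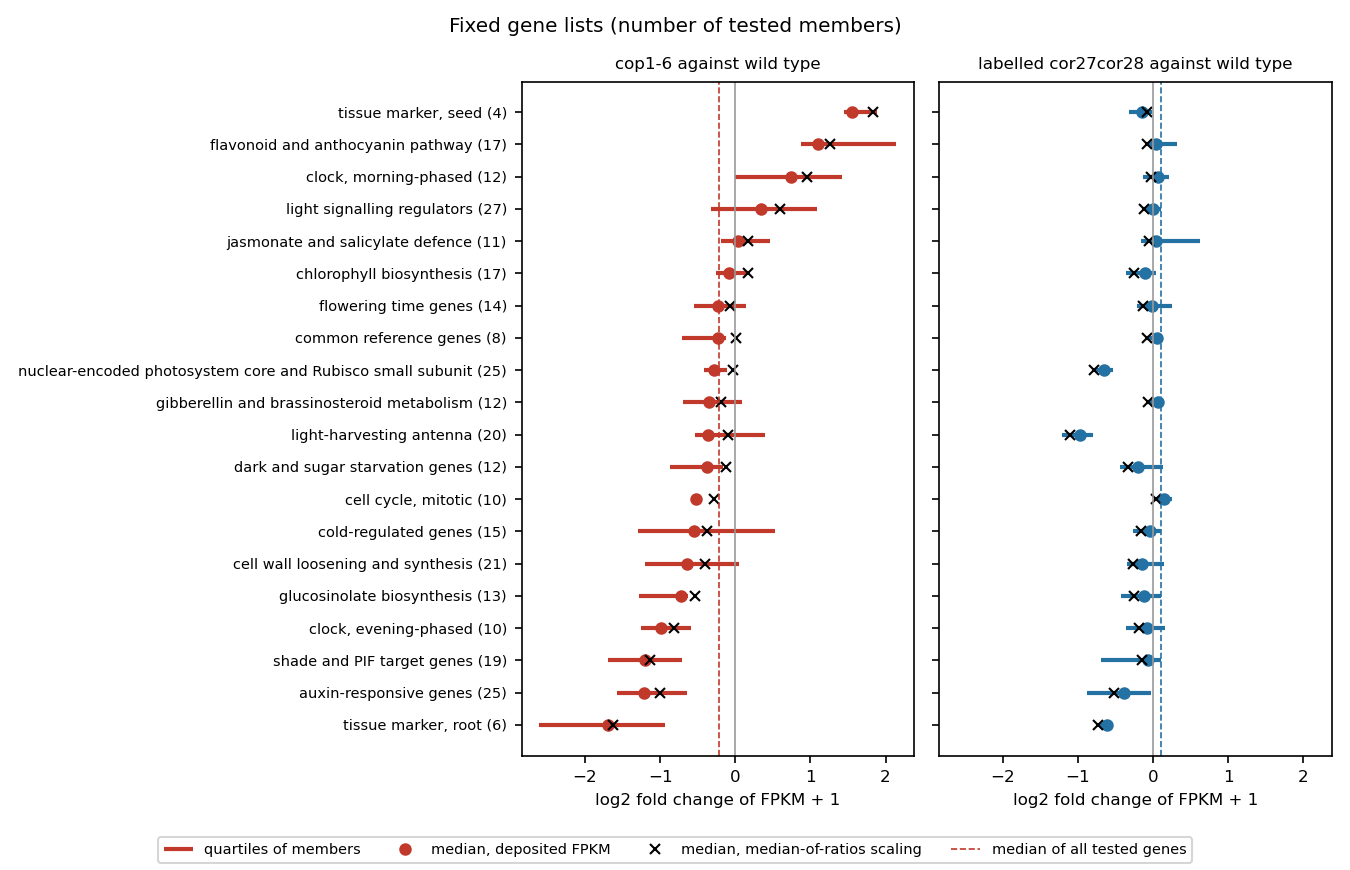
Median log2 fold change of FPKM + 1 over the tested members of 20 gene lists (horizontal axes; the number of members is in parentheses) in cop1-6 (left) and in the libraries labelled cor27cor28 (right) against wild type, with bars from the lower to the upper quartile of the members, crosses for medians with median-of-ratios scaling and a dashed line at the median of all tested genes. In cop1-6 the flavonoid list lay at 1.1 and the auxin-responsive list at −1.22, while the chlorophyll and reference medians changed sign with the scaling, and in the libraries labelled cor27cor28 the antenna list lay at −0.97 and the photosystem core list at −0.65, and the morning clock, gibberellin and brassinosteroid, flavonoid, defence and reference medians changed sign with the scaling.

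The comparison of the libraries labelled cor27cor28 with wild type asks which transcripts depend on COR27 and COR28. Genes of both photosystems and their antennae were lower in these libraries. Of 20 antenna genes, 18 fell and 0 rose, and of 25 photosystem core and Rubisco genes 24 fell and 0 rose. LHCB2.3, an antenna gene of photosystem II, fell from 106 ± 14.7 to 21.5 ± 1.62 FPKM (log2 fold change −2.24 ± 0.14 SE, adjusted p = 5.89e-06). Among genes that rose was ELF4, an evening clock gene, from 2.44 ± 0.112 to 13.3 ± 4.71 FPKM (log2 fold change 2.0 ± 0.20 SE, adjusted p = 0.000141).

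The antenna list had a median log2 fold change of −0.97 (camera adjusted p = 2.1e-29, and adjusted p = 0.113 with an estimated correlation), with 19 lower with median-of-ratios scaling and 18 with equal totals. LHCA4, an antenna gene of photosystem I, fell from 1302 ± 87.7 to 555 ± 8.85 FPKM. LHCB1.2, LHCB1.4 and LHCB1.5 had log2 fold changes of −1.29, −1.27 and −1.33, uncertain one by one because the copies are near-identical. The photosystem core and Rubisco list had a median of −0.65 (camera adjusted p = 6.87e-29, and adjusted p = 0.0876 with an estimated correlation), with 25 lower with median-of-ratios scaling and 23 with equal totals. Its photosystem I genes PSAL, PSAG and PSAD2 fell to 837 ± 39.0, 1440.3 ± 84.6 and 296 ± 24.3 FPKM from 1749 ± 54.6, 2766 ± 73.4 and 528 ± 31.4. Of 17 chlorophyll synthesis genes, 7 fell and 0 rose (camera adjusted p = 0.000578, and adjusted p = 0.293 with an estimated correlation), CRD1 from 1532 ± 75.9 to 1095 ± 24.9 FPKM and HEMA1 from 262 ± 5.29 to 204 ± 4.46 FPKM.

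Some auxin-responsive, shade and cell wall genes fell in these libraries too. Of 25 auxin-responsive genes, 13 fell and 2 rose (camera adjusted p = 7.13e-07, and adjusted p = 0.293 with an estimated correlation), with SAUR20, SAUR21 and SAUR65 at log2 fold changes of −1.21, −1.22 and −0.88, uncertain one by one for the same reason. Of 19 shade and PIF target genes, 7 fell and 1 rose (camera adjusted p = 0.00357, and adjusted p = 0.465 with an estimated correlation). PRE1, a growth-promoting helix-loop-helix gene, fell from 7.90 ± 2.3 to 3.07 ± 1.34 FPKM, and so did HFR1, whose product restrains shade growth, from 15.6 ± 1.63 to 8.49 ± 2.17 FPKM. Of 21 cell wall genes, 7 fell and 2 rose, against 11 and 0 with median-of-ratios scaling and 4 and 3 with equal totals (camera adjusted p = 0.00442, and adjusted p = 0.317 with an estimated correlation), and EXPA8 fell from 71.8 ± 10.8 to 39.0 ± 8.79 FPKM. PIF4 fell from 3.89 ± 0.244 to 1.60 ± 0.573 FPKM (log2 fold change −0.93 ± 0.16 SE, adjusted p = 0.00247). Of 12 gibberellin and brassinosteroid genes, 3 fell and 0 rose, against 1 and 0 with equal totals (camera adjusted p = 0.245), with a positive median (0.06) and a negative mean (−0.01).

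Neither clock list passed. Of 12 morning-phased genes, 1 rose and 2 fell, against 0 and 3 with median-of-ratios scaling and 2 and 1 with equal totals (camera adjusted p = 0.399), with RVE4 falling from 134 ± 4.70 to 83.9 ± 6.74 FPKM. The list's median (0.06) and mean were above 0 and camera placed it below the other genes. Of 10 evening-phased genes, 2 rose and 3 fell, against 2 and 4 with median-of-ratios scaling and 2 and 2 with equal totals (camera adjusted p = 0.239), with a median of −0.08 and a mean of 0.13. PRR5, whose product represses morning clock genes, rose from 1.67 ± 0.555 to 3.91 ± 0.546 FPKM (log2 fold change 0.90 ± 0.18 SE, adjusted p = 0.00516), and LUX fell to 7.45 ± 0.528 FPKM (log2 fold change −0.57 ± 0.10 SE). TOC1 and CCA1 were not called (log2 fold changes 0.19 ± 0.11 and 0.13 ± 0.11 SE). Of 27 light signalling regulators, 2 rose and 2 fell, against 2 and 5 with median-of-ratios scaling and 4 and 2 with equal totals (camera adjusted p = 0.239). The HY5 homolog gene HYH rose from 32.4 ± 2.03 to 58.3 ± 11.4 FPKM, and HY5 was not called (log2 fold change 0.05 ± 0.13 SE).

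Of 15 cold-regulated genes, 4 fell and 1 rose (camera adjusted p = 0.04, and adjusted p = 0.329 with an estimated correlation), and the call was lost with median-of-ratios scaling (adjusted p = 0.129). COR414-TM1 fell to 1.60 ± 0.406 FPKM (log2 fold change −2.09 ± 0.21 SE), while ZAT12, a stress zinc-finger gene, rose from 0.736 ± 0.212 to 3.14 ± 0.353 FPKM. Of 12 dark and sugar starvation genes, 6 fell and 0 rose, against 4 and 2 with equal totals (camera adjusted p = 0.00414, and adjusted p = 0.214 with an estimated correlation), with ASN1, an asparagine synthetase gene, at 4.3 ± 0.599 against 8.83 ± 1.11 FPKM. Of 6 root markers, 3 fell (camera adjusted p = 0.000201, and adjusted p = 0.0876 with an estimated correlation), among them CASP2 and MYB36 with log2 fold changes of −0.68 and −0.55. Of 13 glucosinolate genes, 4 fell and 0 rose (camera adjusted p = 0.04, and adjusted p = 0.293 with an estimated correlation), and the call was lost with median-of-ratios scaling (adjusted p = 0.0851). Of 14 flowering time genes, 1 rose and 3 fell, against 0 and 5 with median-of-ratios scaling and 1 and 2 with equal totals (camera adjusted p = 0.0661), with FLC falling from 6.53 ± 0.999 to 2.46 ± 0.307 FPKM. Of 11 defence genes, 3 rose and 0 fell, against 1 and 0 with median-of-ratios scaling (camera adjusted p = 0.928), PAD3, WRKY33 and JAZ1 with log2 fold changes of 1.35, 0.92 and 0.91. Of 17 flavonoid genes, 2 rose, FLS1 and F3H, against 7 with equal totals and 1 with median-of-ratios scaling (camera adjusted p = 0.718). Of 10 mitotic genes, 1 rose (camera adjusted p = 0.572), CYCB1;1. Of 4 seed markers 0 were called (camera adjusted p = 0.405). Of 8 reference genes 1 fell, ACT2, from 345 ± 12.5 to 216 ± 24.2 FPKM, and with equal totals 2 rose besides (camera adjusted p = 0.472, with a median of 0.06 and a mean of −0.04).

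Among the named genes, the highest fold changes included EARLI1 and AZI1, neighbouring genes of lipid transfer proteins, at 559 ± 43.8 and 1052 ± 51.7 FPKM against 75.1 ± 26.1 and 196 ± 41.2, and UGT74E2, at 15.4 ± 1.57 against 1.72 ± 1.03 FPKM. FTM1, the haemoglobin gene HB1 and ORS1 were also among the highest (log2 fold changes 2.65, 2.46 and 2.28). EARLI1 and AZI1 had 709 and 1076 FPKM in cop1-6 replicate 3, against 132 and 274 in replicate 1 and 60.7 and 147 in replicate 2. MRD1 was among the lowest, at 2.16 ± 0.170 against 11.4 ± 3.39 FPKM.

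In all, 3738 genes were called in this comparison, 2493 higher and 1245 lower in the libraries labelled cor27cor28, and 137 and 52 of them had at least a 2-fold change. Of the called genes 33.3% were lower with the deposited values, 62.8% with median-of-ratios scaling and 16.1% with equal totals. Without replicate 2 of the libraries labelled cor27cor28 the number called was 1834, and without replicate 3 it was 2123. Adjusted over the list alone, the counts above were the same except for 4 evening clock genes, 15 auxin-responsive, 19 antenna, 25 photosystem core, 8 chlorophyll synthesis, 4 flowering time and 5 root genes lower, and for 4 defence genes, 1 flavonoid gene, 1 glucosinolate gene and 0 mitotic genes higher. The medians of the morning clock, gibberellin and brassinosteroid, flavonoid, defence and reference lists turned negative with median-of-ratios scaling, and those of the evening clock, light regulator, cold, flowering time and seed lists turned positive with equal totals. Of the 20 lists, 10 passed with camera, 0 with an estimated correlation and 6 with fry.

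Both mutants were set against the same wild-type libraries, and 507 genes were higher in both and 864 lower in both, while 147 were higher in cop1-6 and lower in the libraries labelled cor27cor28 and 277 the reverse. PIF4, FLC, EXPA8 and COR414-TM1 were lower in both, and UGT74E2, FLS1 and F3H were higher in both. Independent lists of these lengths would share 272, 480.0, 136 and 961 genes. Simulated unchanged groups against the same wild-type values gave a mean of 0.02 genes called in the same direction in both, at most 1, but unchanged groups give almost no calls, so this number does not measure what the shared wild type adds to the overlap. The covariance of both log2 fold changes across genes was 0.0779 against a simulated 0.0108, a difference of 0.0671, and the correlation was r = 0.408 (rho = 0.449) against a simulated 0.5. With 3 wild-type libraries the controls could not be divided, so part of the excess over independent lists may come from the shared controls. Without replicate 2 of the libraries labelled cor27cor28 801 genes were called in the same direction, and without replicate 3 852, against 1371 with all libraries. Leaving out 1 library gave 93 to 160 genes higher in cop1-6 and lower in the libraries labelled cor27cor28, and 107 to 350 the reverse, lowest for both without replicate 2 of those libraries. With median-of-ratios scaling 768 were higher in both, 1107 lower in both, 382 higher in cop1-6 and lower in the libraries labelled cor27cor28, and 28 the reverse.

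**Figure D3:**
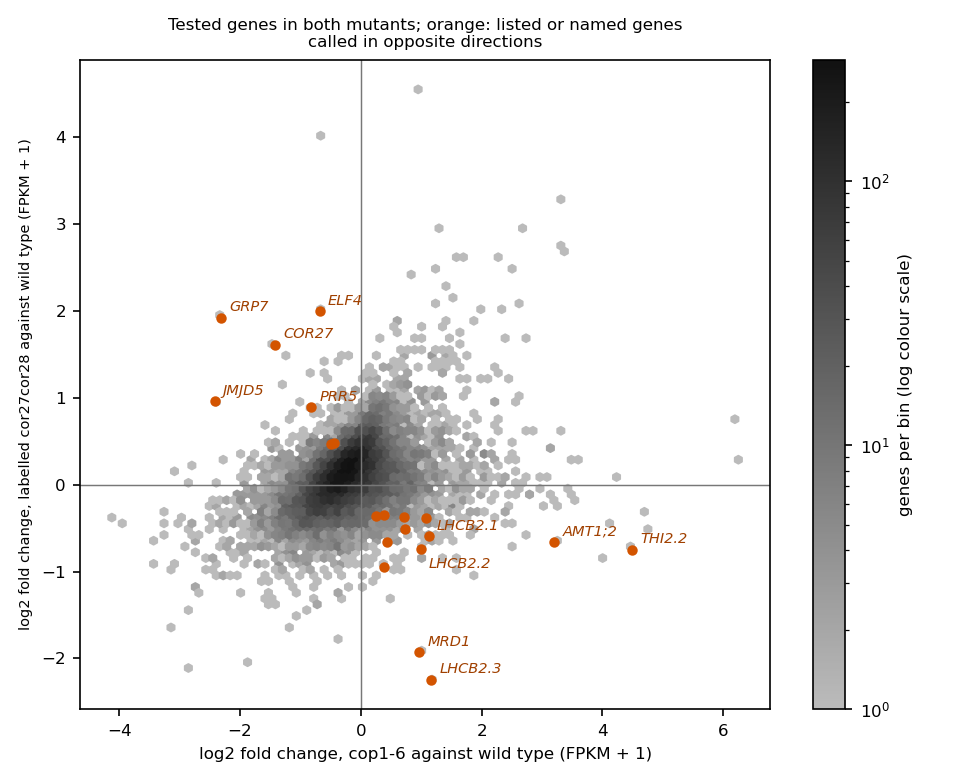
Log2 fold change of FPKM + 1 against wild type in cop1-6 (horizontal axis) and in the libraries labelled cor27cor28 (vertical axis) for the 17075 tested genes, with shading for the number of genes per bin on a log scale and orange points for the 20 listed or named genes called in opposite directions and different between the mutants. GRP7 lay at −2.31 and 1.92 and COR27 at −1.41 and 1.62, while LHCB2.3 lay at 1.16 and −2.24, and with median-of-ratios scaling 17 of the 20 met both conditions.

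Set directly against the libraries labelled cor27cor28, cop1-6 had higher flavonoid, antenna and photosystem transcripts and lower shade-responsive transcripts. All 17 flavonoid genes were higher in cop1-6 (camera adjusted p = 1.08e-23), with CHS at 342 ± 57.1 against 50.9 ± 7.38 FPKM. Of 20 antenna genes 18 were higher and 1 lower (camera adjusted p = 2.6e-20, and adjusted p = 0.122 with an estimated correlation), with LHCB2.3 at 241 ± 47.3 against 21.5 ± 1.62 FPKM (log2 difference 3.41 ± 0.14 SE). Of 25 photosystem core and Rubisco genes 19 were higher and 0 lower (camera adjusted p = 6.51e-18, and adjusted p = 0.122 with an estimated correlation), RBCS3B among them at 1668 ± 163 against 808 ± 103 FPKM. GRP7, a clock-regulated RNA-binding protein gene, was 19.5 times lower in cop1-6, at 28.3 ± 2.77 against 551 ± 52.4 FPKM (log2 difference −4.24 ± 0.09 SE, adjusted p = 1.48e-11).

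Of 12 morning-phased clock genes 8 were higher in cop1-6 and 1 lower (camera adjusted p = 3.28e-08, and adjusted p = 0.122 with an estimated correlation), and of 10 evening-phased genes 1 was higher and 7 lower, which did not pass (camera adjusted p = 0.112) but did with median-of-ratios scaling (adjusted p = 0.00494). ELF4 was at 1.15 ± 0.271 against 13.3 ± 4.71 FPKM and the histone demethylase gene JMJD5 at 1.86 ± 0.306 against 28.9 ± 2.82 FPKM. Of 27 light regulators 13 were higher and 7 lower, against 17 and 4 with median-of-ratios scaling (camera adjusted p = 1.19e-09, and adjusted p = 0.122 with an estimated correlation), BBX32 and BBX24 higher with log2 differences of 3.75 and 1.46, and without cop1-6 replicate 3 the numbers were 11 and 6. PIF4 was not called (log2 difference 0.03 ± 0.16 SE, adjusted p = 0.874). Of 19 shade and PIF targets 13 were lower (camera adjusted p = 0.0388, and adjusted p = 0.501 with an estimated correlation), IAA29 at 0.196 ± 0.115 against 4.66 ± 1.57 FPKM. Of 17 chlorophyll synthesis genes 7 were higher and 6 lower, against 10 and 1 with median-of-ratios scaling and 8 and 4 with equal totals (camera adjusted p = 0.00587, and adjusted p = 0.337 with an estimated correlation), and PORB was at 36.5 ± 0.956 against 509.8 ± 18.2 FPKM. The list's median was 0.06 and its mean −0.11. All 4 seed markers were higher in cop1-6 (camera adjusted p = 3.9e-05, and adjusted p = 0.183 with an estimated correlation). Without cop1-6 replicate 3, where OLEO1 fell short of the FPKM minimum, 3 of them were. That minimum favoured this direction for OLEO1 and CRU1 here too.

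With the evening clock list, 12 lists did not pass with camera. Higher and lower counts were 1 and 19 for auxin-responsive (adjusted p = 0.107), 2 and 15 for cell wall (adjusted p = 0.112), 0 and 9 for glucosinolate (adjusted p = 0.106), 0 and 10 for mitotic (adjusted p = 0.0676) and 0 and 5 for root genes (adjusted p = 0.112). With median-of-ratios scaling they were 2 and 10, 4 and 9, 0 and 6, 0 and 4, and 1 and 4, and all of these lists but cell wall passed (adjusted p = 0.00226 for auxin-responsive, 0.0127 for glucosinolate, 0.0112 for mitotic and 0.00434 for root genes). They were 3 and 6 for cold-regulated (adjusted p = 0.435) and 1 and 5, or 1 and 3 with that scaling, for gibberellin and brassinosteroid genes (adjusted p = 0.86). Flowering time genes had 3 and 6, or 4 and 2 with median-of-ratios scaling (adjusted p = 0.125). Dark and sugar starvation genes had 1 and 5, or 3 and 1 with that scaling (adjusted p = 0.648). Defence genes had 1 and 1, without cop1-6 replicate 3 1 and 5 (adjusted p = 0.112), and reference genes 0 and 5, or 2 and 2 with median-of-ratios scaling and 0 and 3 with equal totals (adjusted p = 0.427). Camera placed the cold, gibberellin and brassinosteroid, flowering time, starvation and defence lists above the other genes, with negative means of −0.25, −0.25, −0.11, −0.31 and −0.14 and, except for a median of 0.07 in the cold list, negative medians. With median-of-ratios scaling the medians of the gibberellin and brassinosteroid, flowering time, starvation, defence and reference lists turned positive, and with equal totals that of the cold list turned negative.

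In all, 11235 genes were called between the mutants, 1569 higher and 9666 lower in cop1-6, and 380 and 683 of them had at least a 2-fold difference. With median-of-ratios scaling 5697 were called, 3300 higher and 2397 lower, so 86.0% of calls were lower with the deposited values, 42.1% with that scaling and 80.2% with equal totals. Adjusted over the list alone, the counts above were the same except for 2 evening clock genes, 14 light regulators, 20 photosystem core genes, 4 flowering time genes and 1 root gene higher and 4 gibberellin and brassinosteroid genes lower. Of the 20 lists, 8 passed with camera, 1 with an estimated correlation and 18 with fry.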

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

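The differences listed here and all tests of explanations in this part were chosen after the results were seen, apart from the divisions of the libraries at its end. Among 312 listed or named genes, 20 were called in opposite directions in the mutants against wild type. These 20 also differed between the mutants in the direct test at an adjusted p under 0.05. This second condition follows from the first, since all comparisons come from the same fit, so it adds no support. With median-of-ratios scaling 17 of the 20 met both conditions, and ELF4, CO and CYCB1;1 did not. Each value below is the log2 fold change in cop1-6 minus that in the libraries labelled cor27cor28.

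Lower in cop1-6 and higher in the libraries labelled cor27cor28 were GRP7 (−4.24), JMJD5 (−3.39), COR27 (−3.03), ELF4 (−2.68), PRR5 (−1.71), the flowering regulator gene CO (−0.95) and the cyclin gene CYCB1;1 (−0.93). Higher in cop1-6 and lower in the libraries labelled cor27cor28 were the chlorophyll synthesis genes HEMA1 (0.62) and CHLH (1.08), the Rubisco gene RBCS2B (0.73), the antenna genes LHCA6 (1.09), LHCB1.1 (1.32), LHCB2.1 (1.72), LHCB2.2 (1.73) and LHCB2.3 (3.41). The same held for the regulator genes CDF3 (1.24) and BBX24 (1.46), for MRD1 (2.89), for the ammonium transporter gene AMT1;2 (3.86) and for THI2.2 (5.23).

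COR27 was weighed first, since its transcript was higher in the libraries that carry its name. A swap of single libraries was excluded by the test used, as 0 of 9 libraries correlated best with a library of another group. An exchange of the labels of all wild-type and all cor27cor28 libraries stayed open, because COR28, which had to move with COR27 or against it, had a log2 fold change of −0.16 and was not called, and it would turn the 2493 higher and 1245 lower genes round and make the 8448 genes called in cop1-6 against wild type a comparison with the double mutant. The listed COR28 values were too low to supply the gain, since the highest in any library was 3.08 FPKM and the COR27 gain 33.3 FPKM. COR28 reads counted under COR27 would be missing from those values, so reads shared with COR28 stayed open. The biological alternative was that evening clock transcripts were higher in general. The evening-phased list as a whole was not, with a median log2 fold change of −0.0774 (quartiles −0.37 to 0.16, and 0.11 with equal totals) against 1.62 for COR27. Of its 10 tested genes 2 rose, ELF4 and PRR5, and 3 fell. A rise of part of the evening genes together with COR27 therefore stayed open.

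Dividing the 6 libraries of each comparison into 3 and 3 in all 10 ways showed 1 division, the real one, with as many called genes as reported. The real numbers were 8448, 3738 and 11235, and the highest other numbers were 0, 1 and 2, and 10 divisions cannot give a p under 0.05. The same held for each comparison, with 1 of 10 divisions for cop1-6, 1 of 10 for the libraries labelled cor27cor28 and 1 of 10 between the mutants. Every other division mixes the genotypes within its groups, which widens the spread there. Few calls in those divisions therefore follow from the design, and no conclusion is drawn from them.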

How the results depend on the processing

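The scalings and the higher minimum mean FPKM were chosen after the unit was seen, and the overlap without single libraries after the results were seen. The other settings were fixed earlier. The number of called genes in cop1-6 against wild type stayed between 7168 and 8550 in all settings, and leaving out 1 library gave 7245 to 8550. The genes themselves changed more. Of the 8448 calls, 5355 kept their call and direction with median-of-ratios scaling and 5875 with equal totals. For the libraries labelled cor27cor28 leaving out 1 library gave 1834 to 4108, the lowest without their replicate 2, and 2123 without their replicate 3, both more than 1.5 times fewer than 3738, and the cause was not tested. Between the mutants it gave 9214 to 11409, and median-of-ratios scaling gave 5697. That scaling moved the median log2 difference of the tested genes from −0.36 to −0.02. With this shift removed, lower calls in cop1-6 went from 9666 to 2397. The cause of the shift itself was not tested. For genes called in the same direction in both mutants leaving out 1 library gave 801 to 1590. The number was 801 without replicate 2 and 852 without replicate 3 of the libraries labelled cor27cor28, and the cause was not tested. With an absolute log2 fold change of at least 1 there were 80, because fewer genes pass. With the replicate number as a replicate block the numbers were 7921, 2967, 10691 and 1129. Libraries with the same number were no more alike than others (r of residuals −0.184 to 0.125).

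Among named genes that were called with the deposited values, only SAND changed sign, between the mutants with median-of-ratios scaling. It was not called there (log2 difference 0.0553, adjusted p = 0.601). Its −0.32 with the deposited values was smaller in size than the median shift of −0.36 that this scaling removed. Sign changes of named genes that were not called are left out here. With no minimum FPKM 10 named genes lost their call, with median-of-ratios scaling 8, as a replicate block 6, with equal totals 4, with a pseudocount of 0.1 3, and in 58 cases on leaving out 1 library. Among the lists, fry called in the direction against camera the chlorophyll list (adjusted p = 0.000368) and flowering time list (adjusted p = 0.027) in cop1-6, and between the mutants the gibberellin and brassinosteroid (adjusted p = 0.00301), chlorophyll (adjusted p = 0.00447), cold (adjusted p = 0.000955) and starvation lists (adjusted p = 0.00717), because fry does not compare a list with other genes. Median-of-ratios scaling changed the call of 8 of 60 list tests, an estimated correlation that of 27, the replicate block that of 1, glucosinolate in the libraries labelled cor27cor28 (adjusted p = 0.0507). Count-based fits, with size factors or library totals and a Wald test, and a count filter were not run because the values are FPKM, and leaving out organelle genes was not run because 0 were present. Depth is not given, so how far it limits genes with low FPKM was not measured.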

Other observations

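The gene families, hypotheses and tests in this part were chosen after the results were seen, apart from the tests on a few very abundant genes and on the condition of cop1-6 replicate 3. The bounds of these were written before their values, though that library was itself picked out from the data. Genes were grouped by the product names of the annotation into 261 families, and of 522 family tests 59 passed with camera and 0 with an estimated correlation (adjusted p = 0.977 for each family named here). Of 12 plasma membrane aquaporin genes, 9 fell and 0 rose in the libraries labelled cor27cor28 (adjusted p = 4.25e-08), with 9 lower with median-of-ratios scaling too. In cop1-6 10 fell and 1 rose, against 7 and 1 with median-of-ratios scaling (adjusted p = 0.0343), and PIP1C had 401 ± 42.7 FPKM in wild type, 195 ± 27.6 in cop1-6 and 266 ± 8.42 in the libraries labelled cor27cor28, with near-identical copies making single values uncertain. Of 25 genes grouped by heat shock in their product name, 14 rose and 0 fell in the libraries labelled cor27cor28, 10 with median-of-ratios scaling (adjusted p = 0.000155). HSP60 rose from 40.6 ± 0.649 to 68.4 ± 6.74 FPKM and HSP81-2 from 51.9 ± 0.736 to 68.9 ± 3.62 FPKM. HSP101 and HSP70 were among those not called in these libraries (log2 fold changes 0.16 and 0.28). Of 12 genes of the TCP-1/cpn60 chaperonin family, which includes chloroplast members, 9 rose and 0 fell there, 5 with median-of-ratios scaling (adjusted p = 0.00212).

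In cop1-6, 27 of 35 genes of the pectin lyase-like superfamily fell and 1 rose, against 21 and 3 with median-of-ratios scaling (adjusted p = 0.00143). PMR6 fell from 118 ± 5.81 to 54.6 ± 8.44 FPKM. Of 37 histone genes 28 fell and 0 rose, against 13 and 1 with median-of-ratios scaling (adjusted p = 0.0048), with a median log2 fold change of −0.55. The dirigent-like gene ESB1, which acts in building the Casparian strip, fell from 13.5 ± 1.26 to 1.92 ± 0.120 FPKM.

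That more genes fell than rose in cop1-6 could come from the scaling of the deposited FPKM, but this stayed open. With median-of-ratios scaling 47.7% of called genes were lower, and that scaling centres the typical gene at no change, so an even split follows from it. For a few very abundant genes as the cause, the 50 most abundant were left out and totals made equal. The median log2 fold change was then −0.0775, below the −0.05 set beforehand as the bound, and 60.5% of called genes were lower. Equal totals alone gave −0.0513, so leaving out these genes did not bring the median nearer to no change. Equal totals themselves had moved it from −0.21. The test therefore cannot separate abundant genes from the scaling, and this cause stayed open. A change in total RNA per seedling was not measured, and no biological explanation was tested.

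In cop1-6 replicate 3, 177 genes were at least 2 times higher than in the other cop1-6 libraries, AZI1 among them, and a condition of that library could account for it, which stayed open. Without that library 15.8% of them (28) were called higher than wild type, against 9.43% of all tested genes. By the bound written beforehand this low share would have counted for such a condition. Since the genes were chosen for being high in that library, a low share does not support it. The biological alternative, the same genes being higher in the libraries labelled cor27cor28, stayed open, because 15.3% of them were, against a median of 11.9% and a 95th percentile of 15.8% for random genes of like expression, and the reading of this test was revised after its value was seen.

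One hypothesis was that the clock stood at a different phase in the mutants at harvest. In cop1-6 the median log2 fold change of 12 morning-phased genes was 0.74 and that of 10 evening-phased genes −0.98, a difference of 1.72 (permutation p = 0.00205). The hypothesis came from these same medians and a single time point cannot separate a shift in phase from a change in level, so it stayed open. In the libraries labelled cor27cor28 the difference was 0.14 (permutation p = 0.401), which leaves it open too.

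Another hypothesis was that sequence from another line linked to the mutations changed genes near COR27 and COR28. Within 1 Mb of them 128 of 704 tested genes were called, 18.2%, against a median of 21.8% for 10000 random pairs of windows (5th to 95th percentile 19.4% to 24.7%, one-sided permutation p = 0.997). Calls were thus no more frequent near these loci than elsewhere. A share over 704 genes cannot show whether a few of them changed through linked sequence, so the hypothesis stayed open. The bound of this test was revised after the value was seen.

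The last hypothesis was that cop1-6 samples held less root, since CASP1 and CASP2 fell. The 8 root hair and uptake genes had a median log2 difference of −0.28 (HAK5 went the other way, from 0.314 to 2.47 FPKM), but 0 of 8 had at least 1 FPKM in wild type (highest 0.780 FPKM), so the test stayed open.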
